A study of Botrytis cinerea with 15 samples.

How the data were processed

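Messenger RNA profiles of mycelia of the grey mould fungus Botrytis cinerea were compared in 15 libraries, 3 from each of 5 groups. Per the labels' protocols, mycelia were grown with shaking in potato dextrose broth for 3 days at 25 °C and then held for 2 h with tea tree oil, 1,8-cineole, terpinen-4-ol or both components together at 0.5 µL/mL, or in broth alone. The labels do not say whether that concentration was of each component or of the mixture in the combined treatment. Every library was assigned to its group from its own label. The labels give no replicate numbers within a group, so those used here follow the order of the samples and pair nothing across groups. The labels also do not say that the 3 libraries of a group came from separate cultures. The p-values therefore measure only the spread between these libraries, which may be technical.

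The values used were FPKM (fragments scaled by transcript length and by the mapped fragments of the library), as computed and deposited by the authors for 11456 loci. TopHat2 and Cufflinks are named, without versions or settings, per the submitters' processing notes. The genome build and the aligner settings are not given in the sources used here. Of the loci, 11126 carry numbered gene IDs and 330 were newly assembled by the authors. A second deposited file gives the positions of those 330 on 142 scaffolds. The positions are printed as that file gives them, on an assembly that it does not name. No FPKM column was without a sample (0 columns).

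The files do not pair the locus IDs with gene names, and 0 of the IDs matched the 11698 genes of the reference table. All 26 gene lists fixed before the data were examined therefore had 0 members, and the planned camera and fry tests of those lists could not be run. Loci are given by their IDs as printed in the files. The fixed rule for such a case took at most 2 IDs that rose and 2 that fell per comparison, by the largest change among loci with an adjusted p under 0.05, no overlap between the 3 and 3 libraries and a mean of at least 10 FPKM in the higher group. Where 5 or fewer loci were called, those outside the rule were named too, and these were chosen after their values were seen.

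Loci with at least 1 FPKM in at least 3 libraries were tested, which kept 9681 loci, 9398 numbered and 283 newly assembled. The values were converted to log2(FPKM + 1), so a fold change is on that scale and understates the change of loci with low FPKM. All 15 libraries entered one fit of group means with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend, two-sided). Benjamini-Hochberg adjustment was made within each comparison, and an adjusted p under 0.05 was called a change. A moderated F test asked which loci differed among the 5 groups. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for descriptions and figures.

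The number of mapped fragments per library cannot be read from FPKM. Steps between low values gave relative depths from 0.835 to 1.16, a ratio of 1.39 between the deepest and the shallowest library, and 96 of 105 pairs of libraries returned a depth ratio within 0.05 log2 of that fit. The fit was tested on simulated data in which every library was drawn around the control mean of each locus. The noise was independent, with the spread of the residuals of that locus. Changes were planted in the tea tree oil group at 200 of 9681 loci, over 20 runs. The changed loci were drawn from those with at least 10 FPKM in control, so the recovery does not extend to loci below that level. Among them it recovered 15.6% of 1.5-fold, 58.0% of 2-fold and 92.3% of 4-fold changes, with 5.53% false calls among all calls. Changes under 2-fold were therefore often missed at this number of libraries. The simulation held no noise shared between loci and no library unlike the rest of its group. Its rates of recovery and of false calls may therefore not hold for the real data.

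Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter, a filter on a mean of at least 5 FPKM, rescaling each library to the same sum, median-of-ratios scaling, quantile normalization, no trend, robust empirical Bayes, a fit of the compared libraries alone, stricter thresholds and leaving out each library of the compared groups in turn. Fits without 3 libraries that stood apart and fits with a weight per library were added after the data were seen. The former leave combination replicate 2 as the only library of its group, so their counts are not given where the combination is compared. Overlaps between treatments share the control libraries, so they are given beside 100 simulations of unchanged groups and beside the overlap of independent lists. Neither can show how much of an overlap comes from the shared controls. Unchanged groups give almost no calls, and independent lists share no controls. With 3 controls, no split into parts of at least 2 libraries was possible.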

Results

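The data describe how the transcript levels of Botrytis cinerea, a necrotrophic fungus that rots fruit and vegetables, differed after exposure to tea tree oil or to its components. Tea tree oil is the distilled leaf oil of Melaleuca alternifolia. The components were 1,8-cineole, a cyclic ether, and terpinen-4-ol, an alcohol, which are isomeric monoterpenoids. There were 15 libraries in 5 groups of 3. The FPKM values of a library summed to between 736627 and 1020006, and between 8554 and 8950 loci per library reached 1 FPKM. Correlations of log2 values across loci had a median of 0.945 within groups and 0.945 between groups, so whole profiles were no closer within groups than between them. Control replicate 3 and combination replicates 1 and 3 stood apart from the other libraries on the first principal component, which held 15.3% of the variance. A single locus, gene4609, took 14.4% and 13.6% of the FPKM in combination replicates 1 and 3 and 6.42% in combination replicate 2.

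**Figure D1:**
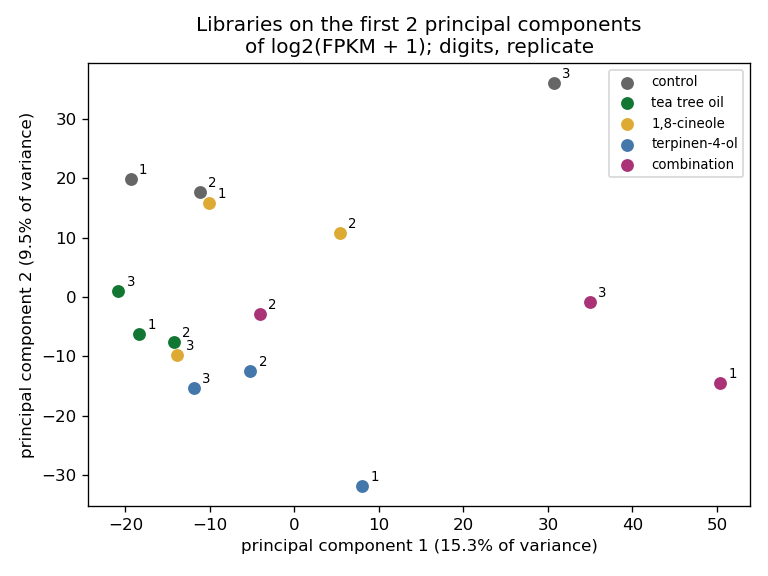
The 15 libraries are placed on the first 2 principal components of log2(FPKM + 1), in arbitrary units, with 15.3% and 9.47% of the variance. Each point is a library and its digit the replicate; control replicate 3 (30.7) and combination replicates 1 (50.4) and 3 (34.9) lie at the right, above every other library on the first component.

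The question of which transcripts responded to the whole oil was addressed by tea tree oil against control. The newly assembled locus Botrytis_cinerea_newGene_402, a 2-exon plus-strand locus at 149221 to 149557 of scaffold NW_001814503.1, rose from 27.7 ± 2.69 FPKM (SD, n = 3) to 343 ± 78.7, a log2 change of 3.56 (SE 0.531, limma adjusted p = 0.0101). The numbered locus gene13840 rose from 5.20 ± 1.43 to 69.5 ± 19.2 FPKM, a log2 change of 3.50 (SE 0.301, adjusted p = 7.43e-05). Among loci that fell, gene4896 went from 21.6 ± 6.59 to 5.87 ± 0.933 FPKM (log2 change -1.69, SE 0.260, adjusted p = 0.0114). The locus gene4398 went from 13.7 ± 1.27 to 4.34 ± 0.727 FPKM (log2 change -1.46, SE 0.202, adjusted p = 0.00633). In total 81 of 9681 loci changed, 60 higher and 21 lower, with median changes of 2.35-fold and 1.94-fold. Medians over called loci, here and below, are of loci chosen by the same test and so tend to overstate the change. The changed loci had a median of 83.3 FPKM against 11.5 for all tested loci, and 3 of them were newly assembled. At an unadjusted p under 0.05 there were 1123 loci, against 484 from chance alone. The call of gene13840 was kept in all 18 alternatives, while Botrytis_cinerea_newGene_402 lost its call in 3 (among them without tea tree oil replicate 2 or 3), gene4896 in 4 (among them the same omissions) and gene4398 in 1 (without tea tree oil replicate 2). The count also fell when single libraries were left out: it was 6 without tea tree oil replicate 2 and 18 without control replicate 2. The loss of power with fewer libraries was not separated from the influence of these libraries.

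For 1,8-cineole, few transcripts could be called. The locus gene5942 rose from 38.6 ± 5.71 to 118 ± 31.5 FPKM (n = 3), a log2 change of 1.57 (SE 0.199, limma adjusted p = 0.0123). The locus gene9825, chosen after its values were seen, was listed at 0 in each of the 12 libraries of the other groups. It stood at 2.77, 3.06 and 7.25 FPKM in the 1,8-cineole libraries (limma adjusted p = 0.0123). The spread behind that p-value is pooled with groups that hold only 0, so it understates that of the 1,8-cineole libraries. These 2 loci, both higher, were the only calls, with 647 loci at an unadjusted p under 0.05 against 484 from chance. Quantile normalization gave 2 higher and 1 lower. The call of gene5942 was lost in 6 of 18 alternatives and that of gene9825 in 5 of the 14 whose filter kept it. No locus was called without 1,8-cineole replicate 1 or without 1,8-cineole replicate 2, which left 0 loci in each case.

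The question of which transcripts responded to terpinen-4-ol alone was addressed by its comparison with control. The locus gene15617 rose from 24.7 ± 2.53 to 106 ± 48.9 FPKM (n = 3; log2 change 1.97, SE 0.270, limma adjusted p = 0.00529). The abundant locus gene12378 rose from 257 ± 115 to 912 ± 432 FPKM (log2 change 1.85, SE 0.396, adjusted p = 0.0456). Lower levels were found for gene12718, from 12.5 ± 5.41 to 2.10 ± 1.85 FPKM (log2 change -2.21, SE 0.488, adjusted p = 0.0496). The locus gene4788 fell from 93.6 ± 24.3 to 32.1 ± 3.66 FPKM (log2 change -1.49, SE 0.218, adjusted p = 0.00936). Together 113 loci changed, 46 higher by a median of 2.41-fold and 67 lower by a median of 1.83-fold, and 1 of them was newly assembled. These medians carry the same overstatement from the choice of loci. Rescaling each library to the same sum turned the balance, with 41 higher and 31 lower. The calls of gene12378 and gene12718 were each lost in 11 of 18 alternatives, and those of gene15617 and gene4788 in 1, the fit of the compared libraries alone. That fit called 1 locus, and the count was 24 without terpinen-4-ol replicate 1.

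In the combined treatment, gene369 stood at 46.5 ± 12.1 FPKM against 11 ± 10.7 in the control (n = 3; log2 change 2.31, SE 0.519, limma adjusted p = 0.0492). The locus gene1102 stood at 918 ± 398 against 204 ± 79.2 FPKM (log2 change 2.13, SE 0.456, adjusted p = 0.0403). Falls were found for gene3416, from 12.3 ± 1.96 to 3.64 ± 1.27 FPKM (log2 change -1.55, SE 0.351, adjusted p = 0.0496). The abundant locus gene15528 fell from 378 ± 45.5 to 130 ± 21.6 FPKM (log2 change -1.54, SE 0.158, adjusted p = 0.00245). Of the tested loci 139 changed, 71 higher and 68 lower, with medians of 2.36-fold and 1.95-fold. Rescaling to the same sum shifted the median of all loci by -0.14 log2 and gave 47 higher and 127 lower, so the direction balance of this group is relative to the scaling. Quantile normalization and median-of-ratios scaling shifted that median by only -0.013 and 0.01 log2. The calls of gene369, gene1102 and gene3416 were lost in 11, 9 and 10 of 18 alternatives, and that of gene15528 in 1. The libraries that stood apart lie in both compared groups. A fit without those 3 leaves only combination replicate 2 in its group, so its count is not given. Without combination replicate 3 the count was 10, and without combination replicate 2 it was 338.

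**Figure D2:**
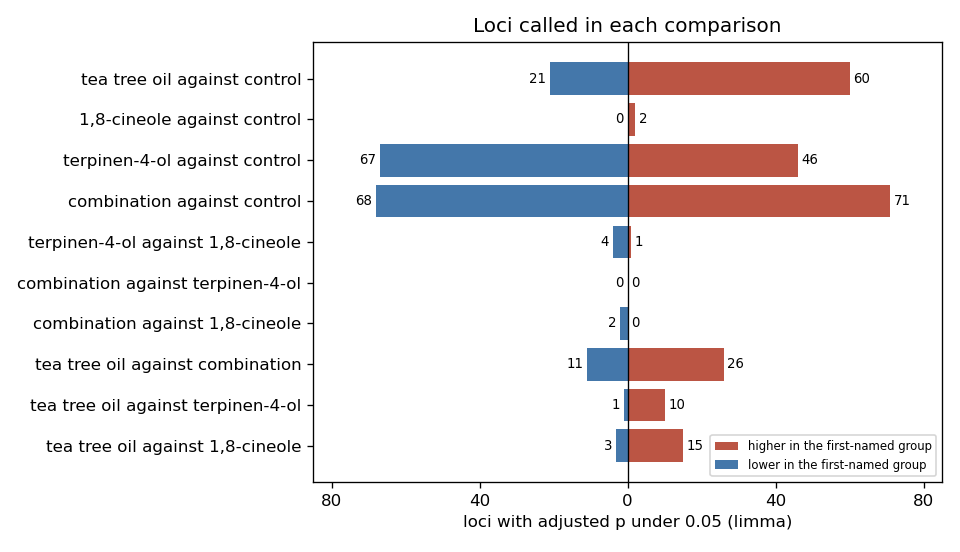
Horizontal bars give the number of loci with a limma adjusted p under 0.05 in each comparison, to the right where the first-named group was higher and to the left where it was lower. Against control, the bars reach 71 higher and 68 lower for the combination, 46 and 67 for terpinen-4-ol, 60 and 21 for tea tree oil and 2 and 0 for 1,8-cineole.

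The isomers were compared directly at the same concentration and time. The locus gene5434 was higher with terpinen-4-ol, at 36.8 ± 1.98 FPKM against 16.8 ± 2.74 with 1,8-cineole (n = 3; log2 difference 1.10, 95% interval 0.78 to 1.41, limma adjusted p = 0.0194). Lower with terpinen-4-ol were gene10824, at 10.2 ± 1.66 against 39.96 ± 17.5 FPKM (log2 difference -1.81, interval -2.42 to -1.20, adjusted p = 0.0465), and gene12777, at 150 ± 22 against 302 ± 25.9 FPKM (log2 difference -1.01, interval -1.31 to -0.71, adjusted p = 0.0194). The other 2 of the 5 loci called, chosen after their values were seen, were gene2230 (log2 difference -0.91, adjusted p = 0.0465) and gene9825, listed at 0 in all terpinen-4-ol libraries. The locus gene5942, higher than control with both isomers, differed between them by -0.08 log2 (interval -0.51 to 0.35). For 6539 of the 9681 loci, 67.5%, the 95% interval of the difference lay within 2-fold either way, with a median interval of 0.54 log2 to each side. These intervals are on the log2(FPKM + 1) scale, which compresses differences at low FPKM. The share may therefore overstate how close loci with low FPKM were. At an unadjusted p under 0.05 there were 1055 loci, against 484 from chance, and rescaling to the same sum gave 1 higher and 1 lower. The calls of gene5434, gene10824, gene12777 and gene2230 were lost in 6, 12, 8 and 13 of 18 alternatives, and that of gene9825 in 4 of 14. No locus was called (0) without terpinen-4-ol replicate 1, and 22 were called without the 3 libraries that stood apart.

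**Figure D3:**
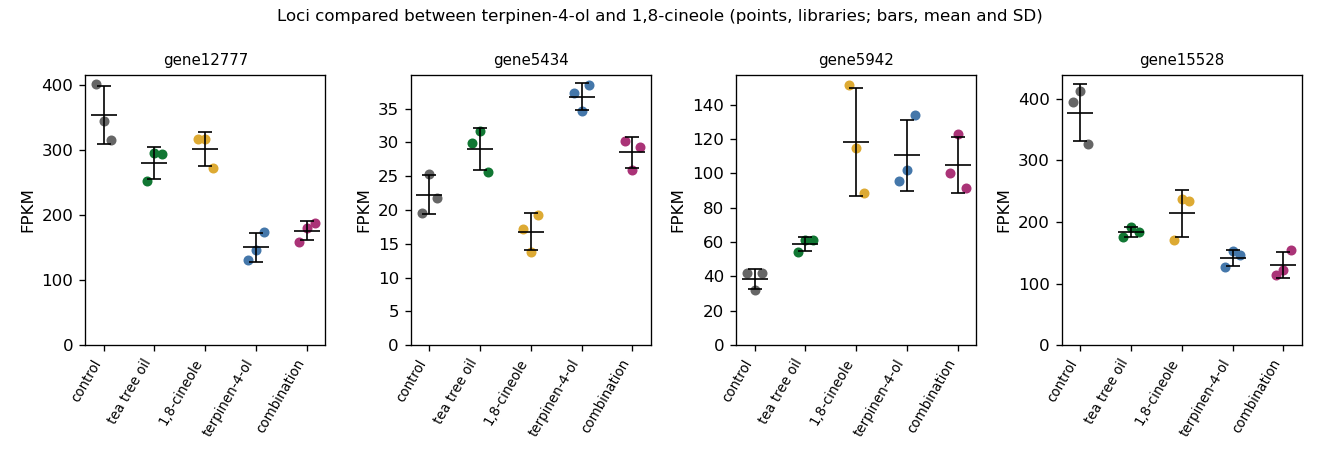
FPKM on a linear axis from 0 is shown for gene12777, gene5434, gene5942 and gene15528 in the 5 groups; points are libraries and bars the mean and SD (n = 3). The terpinen-4-ol mean of gene12777 is 150 FPKM against 302 with 1,8-cineole, while gene5942 stands at 111 and 118 FPKM.

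The combination was set against each component to ask whether the mixture differed from either alone. Against terpinen-4-ol, limma called 0 loci, with 934 at an unadjusted p under 0.05 against 484 from chance. No locus met the naming rule here. Of the loci named for terpinen-4-ol against control, gene4788 differed least, by -0.02 log2 (SE 0.218), at 32.2 ± 8.47 and 32.1 ± 3.66 FPKM (n = 3). The others differed by more: gene12718 by 1.90 log2 (SE 0.488), gene15617 by -0.63 (SE 0.270) and gene12378 by -0.54 (SE 0.396). Against 1,8-cineole, gene8881 was lower in the combination, at 9.83 ± 2.24 against 38.1 ± 14.6 FPKM (log2 difference -1.81, SE 0.260, adjusted p = 0.0477). The other of the 2 loci called was gene9825, chosen after its values were seen and listed at 0 in the combination libraries. At an unadjusted p under 0.05 there were 1304 loci. The call of gene8881 was lost in 9 of 18 alternatives and that of gene9825 in 6 of 14. The 2 calls, both lower, became 23 higher and 36 lower calls with quantile normalization, 8 and 45 after rescaling to the same sum and 1 and 5 with median-of-ratios scaling. Without combination replicate 2, 44 loci were called against terpinen-4-ol and 221 against 1,8-cineole. The change in the combination departed from the sum of the single log2 changes at 0 loci by limma, with 794 at an unadjusted p under 0.05. The median SE of that departure was 0.352 log2, and the concentration of each component in the mixture is not stated, so a sum of doses cannot be assumed.

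The whole oil was set against its 2 components together to ask whether they account for its profile. The locus gene13840 was at 69.5 ± 19.2 FPKM with tea tree oil and 5.83 ± 0.560 with the combination (n = 3; log2 difference 3.33, SE 0.301, limma adjusted p = 0.000265). The locus Botrytis_cinerea_newGene_402 was at 343 ± 78.7 against 38.2 ± 15.4 FPKM (log2 difference 3.17, SE 0.531, adjusted p = 0.0248). Lower with tea tree oil were gene4896, at 5.87 ± 0.933 against 30.8 ± 7.57 FPKM (log2 difference -2.19, SE 0.260, adjusted p = 0.00195), and gene11399, at 1892 ± 194 against 6276 ± 2860 FPKM (log2 difference -1.63, SE 0.315, adjusted p = 0.0486). In all 37 loci differed, 26 higher and 11 lower with tea tree oil, and rescaling to the same sum gave 62 and 10. Among the alternatives, gene13840 kept its call in all 18, while Botrytis_cinerea_newGene_402, gene4896 and gene11399 lost theirs in 6, 1 and 11. The count was 549 without combination replicate 2 and 6 without tea tree oil replicate 3.

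Each component alone was compared with the oil in the same way, and gene13840 was higher with the oil in both comparisons. Against terpinen-4-ol, gene13840 differed by 3.10 log2 (SE 0.301, limma adjusted p = 0.000408) and gene8855 stood at 176 ± 27.6 against 37.2 ± 5.75 FPKM (n = 3; log2 difference 2.21, SE 0.228, adjusted p = 0.000622). The locus gene4896 was lower, at 5.87 ± 0.933 against 25.7 ± 5.25 FPKM (log2 difference -1.95, SE 0.260, adjusted p = 0.00619), and was the 1 lower locus of the 11 called. Against 1,8-cineole, Botrytis_cinerea_newGene_402 differed by 4.21 log2 (SE 0.531, adjusted p = 0.00298) and gene13840 by 3.58 log2 (SE 0.301, adjusted p = 5.66e-05). The newly assembled locus Botrytis_cinerea_newGene_237, at 88049 to 88774 of the plus strand of scaffold NW_001814463.1, was lower at 42.4 ± 1.66 against 79.4 ± 8.25 FPKM (log2 difference -0.89, SE 0.132, adjusted p = 0.0134). There were 18 calls against 1,8-cineole, 15 higher and 3 lower, with 16 and 7 under quantile normalization and 16 and 1 after rescaling to the same sum. A set of 6 loci, gene13840 and gene8855 among them, was higher with tea tree oil than in each of the 4 other groups, and 0 loci were lower than in each. Against terpinen-4-ol, gene13840 and gene8855 kept their calls in all 18 alternatives and gene4896 lost its call in 3. Against 1,8-cineole, Botrytis_cinerea_newGene_402 and gene13840 each lost theirs in 1 of 18 and Botrytis_cinerea_newGene_237 in 6. Without terpinen-4-ol replicate 3 the first count was 32, and without tea tree oil replicate 2 the counts were 6 and 8.

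**Figure D4:**
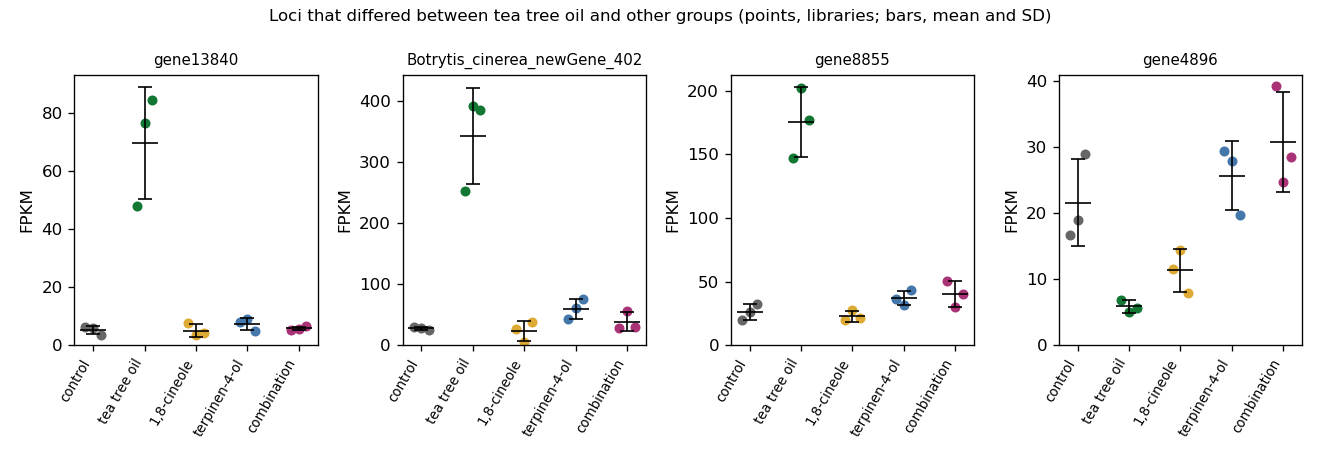
FPKM on a linear axis from 0 is shown for gene13840, Botrytis_cinerea_newGene_402, gene8855 and gene4896 in the 5 groups; points are libraries and bars the mean and SD (n = 3). The tea tree oil means of gene13840 (69.5), Botrytis_cinerea_newGene_402 (343) and gene8855 (176) lie above those of every other group, and that of gene4896 (5.87) lies below them.

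Treatments were also compared by the loci they shared. Terpinen-4-ol and the combination had 32 loci higher in common and 38 lower, where independent lists would share 0.34 and 0.47 and 100 simulations of unchanged groups with shared controls had at most 0 and 1. Among them, gene15528 fell to 142 ± 13.4 FPKM with terpinen-4-ol and gene12777 to 176 ± 14.6 FPKM with the combination (n = 3). Tea tree oil shared 22 higher and 8 lower loci with terpinen-4-ol (0.29 and 0.15 for independent lists) and 26 and 9 with the combination (0.44 and 0.15), against 0 in the simulations, and gene4398 fell in all 3 treatments. Of the 113 loci called for terpinen-4-ol, 90.3% had the same sign with 1,8-cineole, against 58.5% in simulations where the other groups were unchanged, and their median signed change there was 0.36 log2 against 0.99 with terpinen-4-ol and 0.04 in the simulations. Part of these excesses may come from the shared controls. In unchanged groups almost no locus is called, so the simulated overlaps lie near 0 whatever the shared controls do. Independent lists leave the shared controls out. Neither value therefore shows how much of the overlaps the shared controls gave. The simulations of signs planted the called changes at their observed, overstated size, so their calls lean less on noise in the controls. Their 58.5% and 0.04 log2 may therefore be too low a baseline. When each control library in turn was left out of the choice of loci, it lay 0.498, 0.613 and 0.515 of the way from the other controls to the terpinen-4-ol mean, so the called loci rested in part on the control libraries used. In the same fits the 1,8-cineole libraries lay at 0.564 to 0.657, 0.470 to 0.758 and 0.470 to 0.608, ranges close to or including the untreated control held out. The tea tree oil libraries lay at 0.675 to 0.697, 0.798 to 0.831 and 0.626 to 0.729. Those of the combination lay at 0.761 to 0.86, 0.82 to 0.906 and 0.919 to 0.938. Both sets lay above the held-out control in each fit, which is a single library each time. Across all tested loci, the covariance of changes exceeded the simulated one by 0.0359 (jackknife SE 0.0280) for terpinen-4-ol with the combination (0.136 against 0.100), by 0.0395 (SE 0.0357) for tea tree oil with terpinen-4-ol (0.140 against 0.100) and by 0.0244 (SE 0.0223) for 1,8-cineole with terpinen-4-ol (0.125 against 0.101). The excess was 0.0188 (SE 0.0377) for tea tree oil with 1,8-cineole (0.119 against 0.100), 0.0062 (SE 0.0224) for tea tree oil with the combination (0.107 against 0.101) and 0.0064 (SE 0.0310) for 1,8-cineole with the combination (0.107 against 0.101). No excess was over 1.5 times its SE. Correlations across loci were 0.401 for tea tree oil with the combination and 0.442 for 1,8-cineole with the combination, against 0.502 and 0.501 simulated. Tea tree oil had 0.512 with 1,8-cineole and 0.536 with terpinen-4-ol, against 0.502 and 0.501. Terpinen-4-ol had 0.528 with 1,8-cineole and 0.503 with the combination, against 0.501 and 0.499. No SE was computed for these correlations, so differences from the simulated values were not tested.

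Over all 5 groups, 148 loci differed by limma's F test at an adjusted p under 0.05. That count moved when single libraries were left out: it was 23 without control replicate 2 and 278 without combination replicate 2. A fall may also come from the lower power of fewer libraries. The variance of true log2 changes across loci was estimated at 0.0643 (jackknife SE 0.0259) for terpinen-4-ol, 0.0552 (SE 0.0531) for tea tree oil, 0.0756 (SE 0.107) for the combination and 0.0106 (SE 0.0426) for 1,8-cineole. Simulated unchanged groups reached 0.0223, 0.0193, 0.0181 and 0.0161. Those simulations drew loci independently and hold no error shared across loci, so passing them does not show a true change. The estimate for 1,8-cineole lay below even its highest simulated value. The jackknife SE was nearly as large as the estimate for tea tree oil and larger than that for the combination. Differences between treatments in this estimate were not tested.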

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

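Fits without the 3 libraries that stood apart and fits with a weight per library were chosen after the data were seen; all other alternatives were planned. No named locus reversed its direction under any alternative run. This was largely fixed in advance, since the named loci did not overlap between the compared libraries. Leaving out or weighting libraries, or changing the pseudocount, filter or variance model, could not reverse them. Only the scaling alternatives could have done so. Of 546 values for the named loci under these alternatives, 385 kept their side of the threshold and 161 lost it; the losses were most frequent for gene2230 (13 of 18), gene10824 (12 of 18) and gene12378, gene12718, gene369 and gene11399 (11 of 18 each), and gene8855 against terpinen-4-ol had 0. The camera and fry tests of gene lists were not run, since no list had a member. No paired analysis was possible because the labels give no replicate numbers that link libraries across groups. The depth in fragments is unknown, which leaves the precision of low FPKM values open. The causes of the lost calls were not tested, and fits with fewer libraries also have less power.

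In the order tea tree oil, 1,8-cineole, terpinen-4-ol and combination against control, the counts were 81, 2, 113 and 139. A fit of the compared libraries alone gave 26, 0, 1 and 1. An adjusted p under 0.01 left 12, 0, 14 and 4. A 2-fold minimum left 52, 53 and 76 for tea tree oil, terpinen-4-ol and the combination. Weights per library gave 351, 373 and 1997 for the same. Without the 3 libraries that stood apart there were 31 and 0 for tea tree oil and 1,8-cineole. The combination then has only replicate 2, so its count is not given. No trend gave 62 and rescaling to the same sum 72 for terpinen-4-ol. For 1,8-cineole, pseudocounts of 0.1 and 5, a mean of at least 5 FPKM and rescaling each gave 1.

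For terpinen-4-ol against 1,8-cineole (5 loci), pseudocounts of 0.1 and 5 gave 2 and 3, no trend and rescaling 2 each, an adjusted p under 0.01 and the compared libraries alone 0, weights 60 and the fit without the 3 libraries 22. For the combination against terpinen-4-ol (0), no filter and the compared libraries alone gave 1 each and weights 1313. For the combination against 1,8-cineole (2), both pseudocounts, an adjusted p under 0.01 and the compared libraries alone gave 0, no trend 1, median-of-ratios scaling 6, rescaling 53, a mean of at least 5 FPKM 56, quantile normalization 59 and weights 753. For tea tree oil against the combination (37), an adjusted p under 0.01 gave 8, the compared libraries alone 10, no trend 20 and a 2-fold minimum 24. A mean of at least 5 FPKM gave 60, rescaling 72 and weights 2948. For tea tree oil against terpinen-4-ol (11), the compared libraries alone gave 18 and weights 365. For tea tree oil against 1,8-cineole (18), the values were 4 with the compared libraries alone, 9 at an adjusted p under 0.01 and 33 with weights. For the departure from the sum (0), weights gave 9. The F test (148) gave 59 with no trend and 2922 with weights. Counts without the 3 libraries are left out where the combination enters, since only its replicate 2 remains.

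Leaving out each library of the compared groups in turn gave 6 to 54 loci for tea tree oil against control: 18 and 29 without control replicates 2 and 3, and 32, 6 and 10 without tea tree oil replicates 1, 2 and 3. For 1,8-cineole against control it gave 0 to 7: 1 and 7 without control replicates 2 and 3, and 0, 0 and 1 without 1,8-cineole replicates 1, 2 and 3. For terpinen-4-ol against control it gave 24 to 109: 54 and 27 without control replicates 1 and 2, and 24, 40 and 35 without terpinen-4-ol replicates 1, 2 and 3. For the combination against control it gave 10 to 338: 46, 16 and 218 without control replicates 1, 2 and 3, and 17, 338 and 10 without combination replicates 1, 2 and 3. Terpinen-4-ol against 1,8-cineole had 0 to 9: 0 without any 1 of the 1,8-cineole libraries or of terpinen-4-ol replicates 1 and 2, and 9 without terpinen-4-ol replicate 3. The combination against terpinen-4-ol had 0 to 44: 5 without terpinen-4-ol replicate 3, and 1 and 44 without combination replicates 1 and 2. The combination against 1,8-cineole had 0 to 221: 0, 6 and 0 without 1,8-cineole replicates 1, 2 and 3, and 1, 221 and 0 without combination replicates 1, 2 and 3. Tea tree oil against the combination had 6 to 549: 12, 8 and 6 without tea tree oil replicates 1, 2 and 3, and 12, 549 and 7 without combination replicates 1, 2 and 3. Tea tree oil against terpinen-4-ol had 6 to 32: 6 and 7 without tea tree oil replicates 2 and 3, and 6, 6 and 32 without terpinen-4-ol replicates 1, 2 and 3. Tea tree oil against 1,8-cineole had 8 to 17: 8 and 8 without tea tree oil replicates 2 and 3, and 8 and 9 without 1,8-cineole replicates 1 and 2. The departure from the sum had 0 to 1: 1 without control replicate 1 or 3 or combination replicate 2. The F test had 23 to 278: 23 without control replicate 2, 67, 34 and 37 without tea tree oil replicates 1, 2 and 3, 83, 75 and 58 without 1,8-cineole replicates 1, 2 and 3, 76 and 53 without terpinen-4-ol replicates 1 and 2, and 60, 278 and 45 without combination replicates 1, 2 and 3. Rescaling to the same sum shifted the median of all loci by -0.14 log2 for the combination against control, -0.18 for it against terpinen-4-ol, 0.115 for tea tree oil against the combination, 0.10 for terpinen-4-ol against 1,8-cineole and -0.13 for the departure from the sum. The weights ran from 0.367 for combination replicate 2 to 5.33 for combination replicate 3.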

Other observations

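The tests of consecutive ID numbers against library noise and against a joint response were fixed before their result was seen; those of copies, of the sampling of libraries, of the 3 libraries that stood apart and of tea tree oil against the combination were chosen after it. The bound used for relative depth was reworded after the depths were known, and the tests that hold out a library were added after earlier tests of the same explanations had been read.

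Between 5490 pairs of loci with consecutive ID numbers, the covariance of log2 changes with terpinen-4-ol, less the part that library residuals give, was 0.0113, above all 200 shuffled orders (highest 0.00930). Shuffled orders carry no error from the sampling of libraries, so the bound fixed on them was too narrow: the jackknife SE over libraries was 0.0101, and the highest of 9 other splits of the 6 libraries gave 0.00664. The left-over covariance was 0.0163 (SE 0.01) for tea tree oil, 0.0209 (SE 0.0161) for the combination, which holds 2 libraries that stood apart, and 0.00293 (SE 0.00795) for 1,8-cineole. Leaving out pairs whose residuals correlated at 0.5 or more lowered the subtracted part by construction, so the 0.0168 left then decides nothing about copies that share reads. Library noise, such copies and a joint response of neighbours all stay open, and the files do not show that ID order is genome order.

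Control replicate 3 and combination replicates 1 and 3 stood apart on the first principal component. Relative depth argued against depth as the source, since the farthest of the 3 lay 0.0374 from the median of the other 12 libraries and the farthest of those 12 lay 0.165 from it. All 3 kept the 3 highest places after the 100 most abundant loci were left out. A first test of an exchange between groups placed control replicate 3 at 0.511 between the other controls and terpinen-4-ol, over its bound of 0.5, but it could not decide: control replicate 2, held out in the same way, lay at 0.613. With each control held out, the lowest combination library lay at 0.761, above the highest held-out control. The comparison is unequal, since the combination libraries stayed in the fits that chose the loci and only a single control was held out each time. The fits also chose different loci. An exchange, a single wrong label or an unlabelled handling difference therefore stays open, and no biological explanation was tested.

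Tea tree oil differed from the combination at 37 loci, by a median of 1.33 log2 in the direction of the call. The fit without the 3 libraries that stood apart leaves only combination replicate 2 in its group and so cannot decide. The median of the 37 against terpinen-4-ol, 0.85 log2, decides nothing either, since they were chosen on the same tea tree oil libraries. With tea tree oil replicate 1, 2 or 3 held out of the choice, 12, 8 and 6 loci were called. The held-out library differed from terpinen-4-ol by medians of 1.17, 1.99 and 2.03 log2. For those loci this argues against the combination libraries as the source, and it leaves the rest open. Median-of-ratios scaling (median 1.33) moved the median of all loci by only -0.03 log2 and so tested little. Rescaling to the same sum moved it by 0.115 and the calls to 72. The original loci went from 1.11 to 1.25 log2 where higher and from -1.44 to -1.34 where lower. Of the 37, 34 were still called, so most calls outlast this rescaling. A shift of 0.115 log2 is small beside these medians and could hardly have removed them, so scaling as a source stays undecided. A batch shared by the 3 tea tree oil libraries cannot be told apart from the treatment, since the labels give no batch. Other constituents of the oil may contribute, as a hypothesis that the design leaves untested.

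Other splits of the compared libraries are too few, at 10 per comparison, for a share under 0.05. The real and the highest other counts were 81 and 1 for tea tree oil against control, 2 and 4 for 1,8-cineole, 113 and 3 for terpinen-4-ol and 139 and 821 for the combination. The split with 821 set control replicate 3 with combination replicates 1 and 3, and so points to a structure of the samples that the treatment does not explain. Between treatments they were 5 and 2 for terpinen-4-ol against 1,8-cineole, 0 and 2 for the combination against terpinen-4-ol, 2 and 4 for the combination against 1,8-cineole, and 37 and 1, 11 and 2, and 18 and 2 for tea tree oil against the combination, terpinen-4-ol and 1,8-cineole. For the F test, 1 of 100 groupings gave as many loci as the real 148, namely the real one. The highest other gave 67. That is the smallest share 100 groupings can give, and it argues against a chance assignment of libraries as the source of that count. Regrouping cannot separate the treatment from a culture or batch shared by the libraries of a group.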
